A study of Homo sapiens with 14 samples.

How the data were processed

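The measurements are log ratios of RNA amounts from 2-colour DNA microarrays, on which an RNA sample labelled with the dye Cy3 and another labelled with Cy5 compete for the same spots. The RNA came from LNCaP, an established cell line from a human prostate cancer metastasis that responds to androgens. Per the labels, cells were first cultured for 36 h and then kept without steroids for 48 h. They were treated for 24 h with 1 nM R1881 (methyltrienolone, a synthetic androgen), with 25 µg/ml cycloheximide (CHX, a drug that stops protein synthesis on ribosomes), or with both, and RNA was amplified before the dyes were coupled to it. The table holds 14 arrays and 27648 probes per array, with 0 missing values.

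The deposited values are log ratios, taken here as log2, 1 per probe and array. Image analysis, background correction and normalization by the authors are not described in the sources used here. The array medians lie near 0, as they would after centring by the authors. The base of the logarithm is not stated. If it were 10 or e, every log2 value printed here would be larger by a constant factor, while signs, ranks, adjusted p values and calls without a fold limit would be as given. The files hold ratios and no intensities, so dim spots could not be set apart and the signal over background behind each value is unknown.

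The labels name 2 RNAs per array and do not say which is the numerator. The 2 orientations of each dye swap correlated above 0 across probes as deposited in the comparisons with control, so they had already been turned the same way and 1 sign serves for every array. On the direct arrays that correlation was −0.0427, and they were taken to have been turned like the others. The overall sign was taken from the data, by a rule written beforehand. A list of 36 measured androgen-induced genes had a median of −0.21 as deposited in R1881 versus control, with 32 of 36 below 0, so every array was multiplied by −1. A list that shares only SGK1 with the first, immediate-early and short-lived transcripts, had a deposited median of −0.72 in CHX versus control, with 42 of 50 below 0. The androgen-induced list had −0.07 with 28 of 36 below 0 on the arrays that compared CHX plus R1881 with CHX directly. The direction of every signed value is therefore likely, not certain, and a median above 0 of the androgen-induced list in R1881 versus control is not a result in itself.

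Probes were named from their accession through a RefSeq gene table (14721 probes), or else from the platform's symbol, taken as a current symbol (1814), as an older symbol of 1 gene (1085) or kept as it stood (91). This gave 17711 probes with 1 symbol, 0 with several, and 9937 without a name. For 3837 probes the accession led to another symbol than the platform's. The log ratios of probes for the same gene were averaged (2067 of 14533 genes had over 1 probe).

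The 2 arrays of a dye swap compare the same RNA extracts, so they were averaged and counted as 1 replicate, which leaves n = 2 independent culture experiments for each treatment. The resulting 6 log ratios were fitted by limma 3.58.1 in R 4.3.3 with 1 term per treatment against control, 3 residual degrees of freedom and a spread pooled over treatments (moderated with 2.57 prior degrees of freedom). Besides the 3 comparisons with control, 2 contrasts were tested: CHX plus R1881 minus CHX, called R1881 in the presence of CHX, in which the control cancels, and R1881 versus control minus that contrast, called the difference between the R1881 responses without and with CHX. The pooled fit treats log ratios that share a control as independent, so its error for these contrasts is too large where they share a culture. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 14533 genes. Values after ± are the SD between the 2 experiments. The 2 arrays that compared CHX plus R1881 with CHX directly are a dye swap of experiment 1, so they were used as values with no test of their own.

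The comparisons, lists, alternatives and naming rule were chosen before the data were examined. The naming rule took, per comparison, the 10 called genes with the largest rise and the 10 with the largest fall among those with the same sign on all 4 arrays, up to 4 members with the smallest p from each gene list, and a few genes fixed by name, of which KLK3, KLK2, TMPRSS2 and FKBP5 are reported. Other names were chosen after their values were seen, and the text says so where they stand.

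There were 19 gene lists, each tested in limma by camera with a preset correlation of 0.01 between genes, adjusted over the 19 lists within a comparison. Camera asks whether a list ranks above or below other genes. The same lists were tested by camera with a correlation estimated from the data and by fry, which asks whether the members move, on balance, one way. With an estimated correlation camera uses only the 3 residual degrees of freedom, so p rises even where the estimate lies below 0.01. The estimate was −0.0169 for the respiratory chain list, 0.0056 for androgen-induced genes and 0.339 for cell cycle genes. A call lost in that test is thus not by itself a sign of correlated members. Counts of members are given over all genes and adjusted over the list alone. Some members stand in more than 1 list: 5 of 50 immediate-early genes, 5 of the 23 RNAs degraded in step with translation, 4 of 35 ATF4 targets, 4 of 23 p53 targets, 3 of 36 androgen-induced genes, 2 of 10 luminal prostate genes, 1 of 17 androgen-repressed genes and 1 of 13 neuroendocrine genes.

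Correlations across genes were set beside 100 simulations of unchanged treatments that share a control, since a shared control alone correlates the log ratios. Overlaps of calls have no such simulation. Deviations of the experiments from their treatment mean correlated across genes at 0.292 (R1881 and CHX), 0.166 (R1881 and CHX plus R1881) and 0.564 (CHX and CHX plus R1881), so the experiment number pairs the treatments, and fits with the experiment as a block are given beside the counts.

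The fit was tested on simulated data with 14533 genes, of which 200 were changed. For R1881 versus control it called 47.8% of the genes changed by 0.5 on the log2 scale, 92.5% at 1 and 98.5% at 2, with 9 unchanged genes called beside 159 changed ones. For CHX versus control the shares were 35.8%, 85.1% and 98.5%, with 12 unchanged genes beside 146. In the measured data 5519 genes were called with CHX, far more than the 200 changed here, so these shares do not carry over to that comparison. For R1881 in the presence of CHX the shares were 1.49%, 62.7% and 90.9%, with 1 unchanged gene beside 103. The Benjamini-Hochberg threshold is easier to pass when many genes are changed. In the measured data 1 gene was called with R1881 and 0 for R1881 in the presence of CHX. The simulated shares are therefore likely too high for these 2 comparisons. A further fit, to the 4 arrays of each comparison, took each dye-swap pair as a random block (estimated correlation 0.243). It does not pair the treatments of the same experiment. This 4-array fit called 73.1% of the changes of 0.5 in R1881 versus control, but 85 unchanged genes beside 179 changed ones. Unchanged genes thus made up 32.2% of its simulated calls. With 19 simulated lists, of which 1 was shifted by 0.3, camera called that list and 0 others. The simulated genes varied independently of each other, while the measured cell cycle list had an estimated correlation of 0.339 between genes. The simulation therefore cannot tell how often camera calls an unchanged list whose members vary together.

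Alternatives covered normalization (centring, scaling, quantiles), what counts as a replicate, a dye term, each dye orientation alone, the replicate block, leaving out each experiment of each treatment, robust moderation, the summary over probes, the thresholds, the use of the direct arrays and the list test. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Unnamed probes were left out of the comparisons because no gene could be assigned to them. No genome coordinates are given, since the values belong to spots on an array and not to genomic positions.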

Results

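Transcript levels were compared in LNCaP cells that received a synthetic androgen, an inhibitor of protein synthesis, or both. R1881 versus control, CHX versus control and CHX plus R1881 versus control were each measured on 4 arrays, from 2 independent culture experiments hybridised in both dye orientations. CHX plus R1881 was also compared with CHX directly on 2 arrays, a dye swap of experiment 1. The log ratios of each array were summarised to 14533 named genes. The SD of the log2 ratios over probes was 0.18 to 0.25 on the R1881 arrays, 0.57 to 0.62 on the arrays with CHX against control, and 0.13 and 0.20 on the direct arrays. Across all probes, the arrays of an R1881 dye swap correlated at r = 0.134 in experiment 1 and 0.216 in experiment 2, those of CHX at 0.882 and 0.788, those of CHX plus R1881 at 0.893 and 0.830, and the direct arrays at −0.0427. Probes are not independent replicates. The number of experiments, 2 per treatment, limits the precision of every value.

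The comparison of R1881 with control asks which transcripts respond to androgen within 24 h. TMPRSS2, a membrane serine protease gene that androgens induce in prostate cells, rose by 1.65 ± 0.17 on the log2 scale (3.15-fold, n = 2 experiments, above 0 on 4 of 4 arrays, limma adjusted p = 0.0202). KLK3, which encodes prostate-specific antigen, had 0.98 ± 0.01 (adjusted p = 0.126), and its neighbour KLK2 had 0.77 ± 0.17 (adjusted p = 0.126). FKBP5, a co-chaperone of steroid receptors, had 0.69 ± 0.12 (adjusted p = 0.261). The KLK3 value averages 3 probes, with 1.49, 1.81 and −0.36, and that of KLK2 averages 2 probes, with 1.65 and −0.12, so the probes of each gene differed in sign. When each probe was tested alone, KLK3 was called besides TMPRSS2, with 1.81 at an adjusted p of 0.00641.

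Among 48 measured genes of the cell cycle and DNA replication, 47 were above 0 with R1881, and the list rose with a median of 0.34 (camera adjusted p = 5.13e-24; adjusted p = 0.148 with an estimated correlation). TPX2, a spindle assembly factor, had 0.70 ± 0.04, MCM4, a subunit of the replicative helicase, 0.51 ± 0.20, TYMS, thymidylate synthase, 0.40 ± 0.03, and ORC1, an origin recognition subunit, 0.38 ± 0.13. None of the 48 passed over all genes, and 13 rose when adjusted over the list alone. Of the 36 androgen-induced genes, 32 were above 0 (median 0.21; camera adjusted p = 1.78e-17, and 0.0496 with an estimated correlation), a direction that served to set the sign of the data. In that list 1 gene, TMPRSS2, rose over all genes and 10 rose when adjusted over the list alone, while C1orf116 had 0.78 ± 0.05 (adjusted p = 0.126). Androgen-repressed genes fell as a list, with a median of −0.14 and 4 of 17 above 0 (adjusted p = 0.00133; adjusted p = 0.148 with an estimated correlation). UGT2B15, which conjugates androgens, had −0.47 ± 0.21, FOLH1, prostate-specific membrane antigen, −0.48 ± 0.34, and SI, sucrase-isomaltase, −0.37 ± 0.24, while TMEFF2 had 0.34 ± 0.03. With the list alone, 1 of the 17 fell, and the list was not called from the arrays with the first-named RNA in Cy3 alone (adjusted p = 0.161).

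Transcripts of cytoplasmic ribosomal proteins fell as a list with R1881, with a median of −0.15 and 3 of 63 above 0 (adjusted p = 1.58e-11; adjusted p = 0.148 with an estimated correlation), and 0 of the 63 passed one by one in limma. RPL34 had −0.24 ± 0.10 and RPS15A −0.31 ± 0.24. Replication-dependent histone genes also fell as a list (median −0.11, 10 of 37 above 0, adjusted p = 1.05e-05; adjusted p = 0.148 with an estimated correlation), with 2 of 37 that fell when adjusted over the list alone. H1-2, a linker histone, had −0.46 ± 0.05, and H2BC9 had 0.63 ± 0.22. The respiratory chain list fell (median −0.10, 9 of 44 above 0, adjusted p = 9.98e-06; adjusted p = 0.106 with an estimated correlation), but not from the arrays with the first-named RNA in Cy3 alone (adjusted p = 0.106). COX6C, a subunit of cytochrome oxidase, had −0.29 ± 0.01.

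Genes of ribosome biogenesis rose as a list with R1881 (median 0.10, 27 of 29 above 0, adjusted p = 6.41e-06; adjusted p = 0.148 with an estimated correlation), with LYAR at 0.33 ± 0.02 and NOP14 at 0.32 ± 0.07. So did chaperones of the endoplasmic reticulum (median 0.11, 28 of 33 above 0, adjusted p = 3.12e-05; adjusted p = 0.267 with an estimated correlation), with HSPA5, the chaperone BiP, at 0.42 ± 0.07 and HSP90B1 at 0.35 ± 0.16. Without experiment 1 of R1881 the chaperone list was not called (0.09, adjusted p = 0.0807). The other 11 lists were not called by camera in this comparison. That of luminal prostate genes had a median of −0.05 and a mean of 0.01, ranked down by camera and up by fry. That of ATF4 targets had a median of 0.02 and a mean of −0.02. Fry called 1 of the 19 lists with R1881, that of androgen-induced genes (adjusted p = 0.00516). Its adjusted p was 0.0865 for the androgen-repressed, histone, respiratory chain and ribosome biogenesis lists. For cell cycle, ribosomal protein and chaperone genes it was 0.0959, 0.103 and 0.317.

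**Figure D1:**
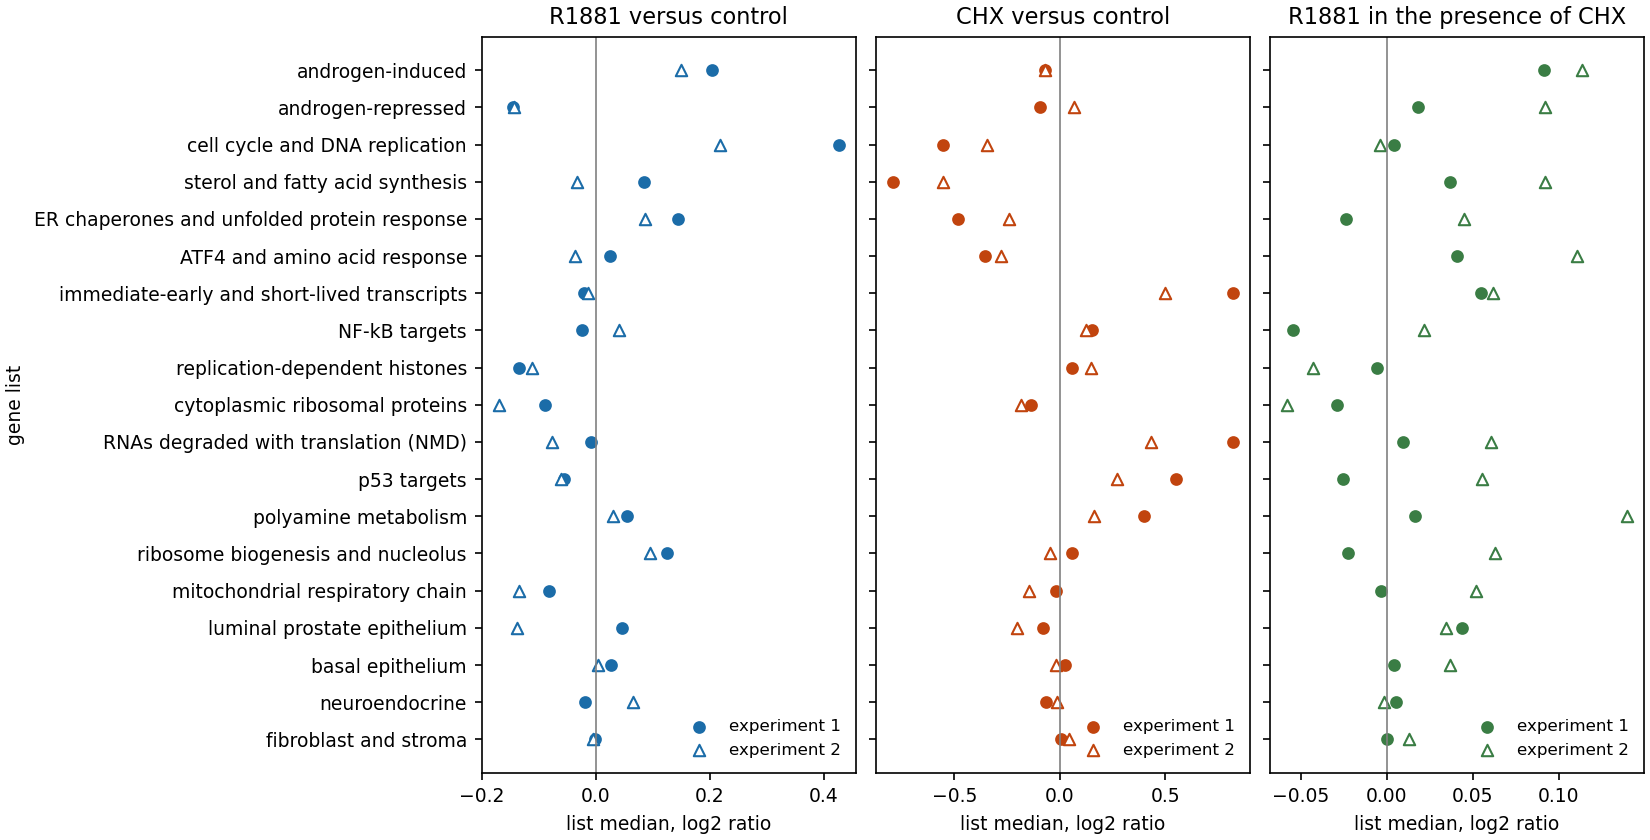
Median log2 ratio of each of the 19 gene lists in R1881 versus control, CHX versus control and R1881 in the presence of CHX. Circles are experiment 1 and triangles experiment 2, each the mean of a dye swap; the 3 horizontal scales differ, and the cell cycle list lies at 0.43 and 0.22 with R1881 alone and near 0 with R1881 in the presence of CHX.

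Over all genes limma called 1 gene with R1881 (1 rose, 0 fell), while 921 genes had an unadjusted p under 0.05 against 727 expected by chance. With the experiment as a block it called 2, TMPRSS2 and SCD5, and with either experiment of R1881 left out it called 0, as TMPRSS2 then had an adjusted p of 0.0947 without experiment 1 and 0.270 without experiment 2. The fit to 4 arrays with a random block called 172 (104 rose, 68 fell), but 32.2% of the calls of this fit were unchanged genes in simulated data, and its names below were chosen after their values were seen. Besides TMPRSS2, the largest changes among its calls were those of TRPM8, a cold-sensing ion channel with prostate expression, at 1.80 ± 0.65 (adjusted p = 0.188 with the swaps averaged and 0.000187 in the 4-array fit), TM4SF1, a membrane protein, at 1.69 ± 0.01 (0.126 and 0.000161), SCD5, a stearoyl-CoA desaturase, at 1.46 ± 0.28 (0.118 and 0.000161), and GNG3, a G protein subunit, at 1.38 ± 0.34 (0.126 and 9.60e-05). KLK3, KLK2 and FKBP5 were among the 104. The lowest values among the 68 were those of the nuclear noncoding RNA MALAT1 at −0.87 ± 0.30 (0.188 and 0.00350) and of MYNN at −0.71 ± 0.07 (0.212 and 0.000529); NEAT1, another nuclear noncoding RNA, had −0.61 ± 0.16 (0.609 and 0.0344).

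The comparison of CHX with control shows how these transcripts differ after 24 h with the inhibitor, and is the background for R1881 given together with CHX. How far protein synthesis was stopped was not measured. ACTA2, smooth muscle actin, rose by 4.78 ± 0.23 (27.5-fold, n = 2 experiments, adjusted p = 4.03e-05), and MT2A, a metallothionein, by 4.08 ± 0.34. FHL2, a LIM-domain coactivator, rose by 3.88 ± 0.17, MAP3K14, a kinase of the NF-kB pathway, by 3.91 ± 0.12, FOS, an immediate-early transcription factor, by 3.56 ± 0.60, and EDN1, endothelin 1, by 3.47 ± 0.11. PXDC1 (4.10 ± 0.28), SERTAD4 (4.04 ± 0.10), TCIM (3.88 ± 1.04) and TUFT1 (3.60 ± 0.22) complete the 10 largest rises. Among the falls, RLN1, which encodes the hormone relaxin, had −3.84 ± 0.04, the antioxidant genes PRDX1 and SOD1 had −3.66 ± 0.63 and −3.05 ± 0.71, DDIT4, an inhibitor of mTORC1, −3.69 ± 1.5, and TMEFF2 −3.01 ± 0.13. The other 5 of the 10 largest falls are ribosomal protein genes: RPS2 at −4.09 ± 0.96, RPS3 at −3.62 ± 0.82, RPL12 at −3.50 ± 0.91, RPL29 at −3.40 ± 0.89 and RPL4 at −3.22 ± 0.17.

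In CHX versus control, immediate-early and short-lived transcripts rose as a list (median 0.72, 42 of 50 above 0, 31 rose and 2 fell; camera adjusted p = 3.33e-07, adjusted p = 0.383 with an estimated correlation). Adjusted over the list alone, 33 rose and 2 fell, and JUN rose by 2.55 ± 0.07, SRF by 2.40 ± 0.14, KLF6 by 2.25 ± 0.10 and GADD45B by 2.13 ± 0.12. RNAs that are degraded in step with translation rose as a list (median 0.65, 12 of 23 rose and 1 fell, the same adjusted over the list alone; adjusted p = 0.000794, and adjusted p = 0.383 with an estimated correlation), with rises of ATF4 by 1.77 ± 0.14, GADD45A by 2.06 ± 0.37 and DDIT3 by 0.81 ± 0.01, which also stand in other lists. That list was drawn up with 34 members, and those not measured include SNHG1, SNHG3, SNHG5, SNHG6, SNHG8, SNHG12, SNHG15, SNHG16 and ZFAS1. Its rise therefore rests on the other 23. From the arrays with the first-named RNA in Cy3 alone ATF4 had 0.61 and was not called (adjusted p = 0.0827). Cell cycle genes fell (median −0.43, 25 of 48 fell and 2 rose; adjusted over the list alone 27 fell and 3 rose; adjusted p = 5.73e-07, and adjusted p = 0.383 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 2.80 ± 0.42, with CDK1, the mitotic kinase, at −1.52 ± 0.09 and PCNA, the replication clamp, at −1.18 ± 0.03. Genes of sterol and fatty acid synthesis fell (median −0.61, 19 of 31 fell and 1 rose, SC5D, by 2.04 ± 0.19; adjusted over the list alone 21 fell and 2 rose; adjusted p = 1.53e-06, and adjusted p = 0.383 with an estimated correlation). In it FADS1, a fatty acid desaturase, had −1.66 ± 0.06, EBP, a sterol isomerase, −1.48 ± 0.24 and FASN, fatty acid synthase, −1.37 ± 0.11.

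Chaperones of the endoplasmic reticulum fell as a list with CHX (median −0.35, 18 of 33 fell and 3 rose; adjusted over the list alone 19 fell and 4 rose; adjusted p = 0.00261, and adjusted p = 0.383 with an estimated correlation). MANF, a secreted stress-induced protein of that compartment, had −1.96 ± 0.07, HERPUD1 −1.72 ± 0.15 and XBP1, a transcription factor of the unfolded protein response, −1.21 ± 0.25. Cytoplasmic ribosomal protein genes fell as a list (median −0.18, 24 of 63 fell and 8 rose; adjusted over the list alone 26 fell and 9 rose; adjusted p = 0.0109, and adjusted p = 0.424 with an estimated correlation). Their list was not called without experiment 2 of CHX (−0.13, adjusted p = 0.0557), and from the arrays with the first-named RNA in Cy5 its median was 0.03. RPLP0 had −2.67 ± 0.36, RPL22 −1.19 ± 0.02 and RPL34 −1.01 ± 0.06. Targets of ATF4 in amino acid supply had a median of −0.26 (18 of 35 fell and 9 rose; adjusted over the list alone 19 fell and 10 rose; adjusted p = 0.0299, and adjusted p = 0.458 with an estimated correlation). AARS1, alanyl-tRNA synthetase, had −2.02 ± 0.06 and SLC1A5, a glutamine transporter, −1.40 ± 0.12, while ATF3, itself a transcription factor of the stress response, rose by 2.87 ± 0.35.

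Targets of p53 rose as a list with CHX (median 0.28, 10 of 23 rose and 3 fell; adjusted over the list alone 11 rose and 4 fell; adjusted p = 0.0299, and adjusted p = 0.383 with an estimated correlation). Their list median was 0.55 in experiment 1 and 0.27 in experiment 2. FAS, a death receptor, rose by 2.53 ± 0.51, TNFRSF10B, another death receptor, by 1.34 ± 0.00, and XPC, a DNA repair protein gene, by 1.22 ± 0.10. Histone genes rose (median 0.16, 13 of 37 rose and 3 fell, the same adjusted over the list alone; adjusted p = 0.0299, and adjusted p = 0.383 with an estimated correlation), with H2BC5 up by 1.53 ± 0.09 and H1-2 down, at −1.37 ± 0.14. NF-kB targets rose (median 0.20, 9 of 30 rose and 3 fell; adjusted over the list alone 11 rose and 3 fell; adjusted p = 0.0470, and adjusted p = 0.383 with an estimated correlation). In that list NFKBIA, the inhibitor of NF-kB, rose by 1.56 ± 0.01, NFKBIE by 1.32 ± 0.18 and NFKB1 by 1.13 ± 0.03. Without experiment 1 of CHX the lists of p53 targets (0.27, adjusted p = 0.116), NF-kB targets (0.12, adjusted p = 0.141) and ATF4 targets (−0.28, adjusted p = 0.0980) were not called, and without experiment 2 that of histones was not (0.06, adjusted p = 0.0710). Quantile normalization ended the calls of the NF-kB list (0.16, adjusted p = 0.0655) and the ATF4 list (−0.19, adjusted p = 0.0503). The arrays with the first-named RNA in Cy3 alone ended those of the NF-kB (0.23, adjusted p = 0.113), ATF4 (−0.32, adjusted p = 0.0609) and histone lists (0.09, adjusted p = 0.104).

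Androgen-induced genes went both ways with CHX alone (median −0.06, 8 of 36 rose and 13 fell; 9 rose and 14 fell adjusted over the list alone; camera adjusted p = 0.218). Fry called the list down (adjusted p = 0.0103). KLK3 fell by 1.54 ± 0.19 and NDRG1 fell by 2.46 ± 0.18, TMPRSS2 had 0.23 ± 0.05 (adjusted p = 0.0614) and FKBP5 had −0.09 ± 0.22 (adjusted p = 0.590). KLK2 fell by 0.42 ± 0.03 (adjusted p = 0.00810), but not after scaling (−0.31, adjusted p = 0.283), after quantile normalization (−0.33, adjusted p = 0.0736), without experiment 1 (−0.44, adjusted p = 0.0502) or without experiment 2 (−0.40, adjusted p = 0.0549) of CHX. FOXA1, a pioneer transcription factor, had −2.02 ± 0.02, HOXB13, a prostate homeobox gene, −1.69 ± 0.19 and ACP3, prostatic acid phosphatase, −2.89 ± 0.61, and each of these 3 fell.

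Limma called 5519 of 14533 genes with CHX (2982 rose, 2537 fell), against 6542 with the experiment as a block. Of 354 genes with at least 2 called probes, 54 had called probes in opposite directions. A change of at least 1.5-fold was met by 2985 genes. Of the 19 lists, camera called 10 with CHX, 0 with an estimated correlation, and fry called 16.

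CHX plus R1881 versus control asks for the sum of both treatments, and its largest changes overlapped those of CHX. ACTA2 rose by 4.66 ± 0.06, PXDC1 by 4.25 ± 0.15, MT2A by 3.99 ± 0.12, TCIM by 3.96 ± 0.60, SERTAD4 by 3.86 ± 0.01, MAP3K14 by 3.85 ± 0.37, FHL2 by 3.72 ± 0.06, FOS by 3.60 ± 0.10, TUFT1 by 3.58 ± 0.22 and EDN1 by 3.54 ± 0.25. RPS2 (−3.90 ± 0.85), RPL12 (−3.62 ± 1.06), RPS3 (−3.59 ± 0.87), PRDX1 (−3.47 ± 0.45), DDIT4 (−3.45 ± 1.25), RPL29 (−3.21 ± 0.91), RPL4 (−3.16 ± 0.26), RLN1 (−3.15 ± 0.46), SOD1 (−2.96 ± 0.80) and ADAM2, a sperm surface protein gene (−2.91 ± 0.39), fell most. DDIT4 was not called without experiment 1 of CHX plus R1881 (−2.56, adjusted p = 0.0690). TMPRSS2 had 0.54 ± 0.05 (adjusted p = 0.00341), a call lost after scaling (0.44, adjusted p = 0.331) and after quantile normalization (0.42, adjusted p = 0.122). KLK3 fell by 1.25 ± 0.07 (adjusted p = 0.000272), KLK2 had −0.24 ± 0.04 (adjusted p = 0.0563) and FKBP5 had 0.17 ± 0.21 (adjusted p = 0.308).

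With CHX plus R1881 camera called 6 lists: immediate-early transcripts (median 0.71, adjusted p = 2.02e-08) and RNAs degraded in step with translation (0.76, adjusted p = 0.000342) rose, and cell cycle (−0.43, adjusted p = 9.60e-08), sterol synthesis (−0.51, adjusted p = 1.04e-05), ribosomal protein (−0.17, adjusted p = 0.000462) and chaperone genes (−0.34, adjusted p = 0.00114) fell. Each of the 6 had an adjusted p = 0.382 with an estimated correlation, while fry called 13 of the 19 lists. Among these lists 31 of 50, 13 of 23, 2 of 48, 3 of 31, 6 of 63 and 4 of 33 members rose, and 2, 2, 27, 18, 26 and 17 fell. Adjusted over the list alone 35, 13, 2, 3, 7 and 5 rose, and 2, 2, 31, 20, 27 and 19 fell. The ribosomal protein list was not called from the arrays with the first-named RNA in Cy5 (−0.05, adjusted p = 0.0820). Targets of p53 were called with the experiment as a block (0.28, adjusted p = 0.0299; 0.382 without the block and with an estimated correlation). The androgen-induced list had a median of 0.02 and a mean of 0.04 and was ranked down by camera (adjusted p = 0.655), with 11 of 36 that rose and 11 that fell, and 13 and 15 adjusted over the list alone.

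Limma called 5443 genes with CHX plus R1881 (3028 rose, 2415 fell), against 6432 with the experiment as a block and 3402 without its experiment 1. Across genes, the mean changes with CHX and with CHX plus R1881 correlated at r = 0.975, against 0.498 for simulated unchanged treatments that share a control, and at 0.900 and 0.882 when each came from a different experiment. Genes that rose in both numbered 2709 and genes that fell in both 2184, and 1 gene was called in opposite directions. Independent calls would give 621 and 422, but calls that share a control are not independent, so these overlaps have no chance value here. As the spread of the changes differs from the simulated one, covariances were compared too: 0.328 for CHX and CHX plus R1881 against 0.00577 simulated. The covariance of R1881 versus control and CHX versus control was 0.00554, against 0.00577 in the simulation.

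**Figure D2:**
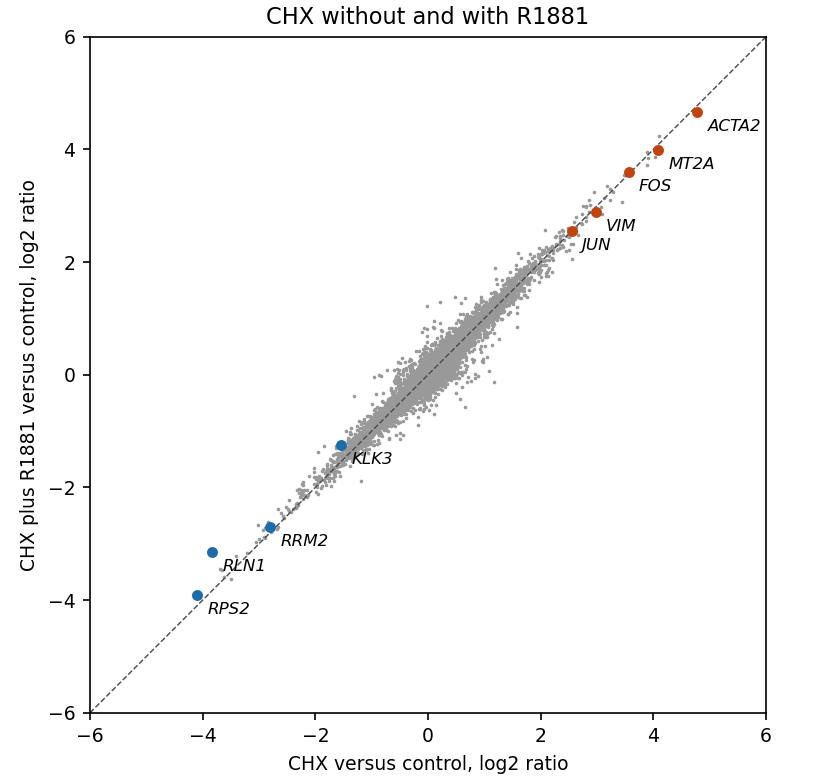
Log2 change of each gene with CHX versus control (horizontal) against CHX plus R1881 versus control (vertical), each point the mean of 2 experiments, with 9 genes labelled and a dashed line where both changes are equal. The points lie along that line (r = 0.975 across genes), and ACTA2 is at 4.78 and 4.66.

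R1881 in the presence of CHX asks which transcripts respond to androgen when CHX is given to keep new protein from acting in between. It is the test for direct targets that the series title names, and it assumes that CHX stopped protein synthesis. C1orf116, an androgen-responsive gene of unknown function, had 0.87 ± 0.06 with CHX and 0.78 ± 0.05 without it, and 0.88 and 0.92 on the direct arrays. ZBTB16, a zinc finger transcription factor induced by several steroid hormones, had 0.77 ± 0.04 with CHX and 0.63 ± 0.13 without it, and 0.67 and 0.87 on the direct arrays. These were the 2 genes called by the 4-array fit (adjusted p = 0.00965 for both), and they also were among its 104 in R1881 versus control. The fit with averaged swaps called neither, and ZBTB16 was chosen after its values were seen. TRPM8 had 0.86 ± 0.03 with CHX and 1.01 and 0.98 on the direct arrays, and STEAP2, a metalloreductase gene, had 0.37 ± 0.27 with CHX and −0.27 ± 0.12 without it.

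Of the genes named by the rule, TMPRSS2 had 0.31 ± 0.00 in the presence of CHX (0.44 and 0.31 on the direct arrays), KLK3 had 0.29 ± 0.12 (0.25 and 0.25), KLK2 had 0.18 ± 0.01 (0.08 and 0.13) and FKBP5 had 0.26 ± 0.01 (0.19 and 0.17). For TMPRSS2 the difference between the R1881 responses without and with CHX was 1.35 ± 0.17 (adjusted p = 0.610, and 0.000620 in the 4-array fit). SCD5, chosen after its values were seen, had 1.46 ± 0.28 without CHX, −0.44 ± 0.05 with CHX, −0.33 and −0.29 on the direct arrays, and a difference of 1.90 ± 0.33 (adjusted p = 0.610, and 0.00969 in the 4-array fit). TM4SF1 had 0.02 ± 0.47 and GNG3 had 0.16 ± 0.09 with CHX.

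**Figure D3:**
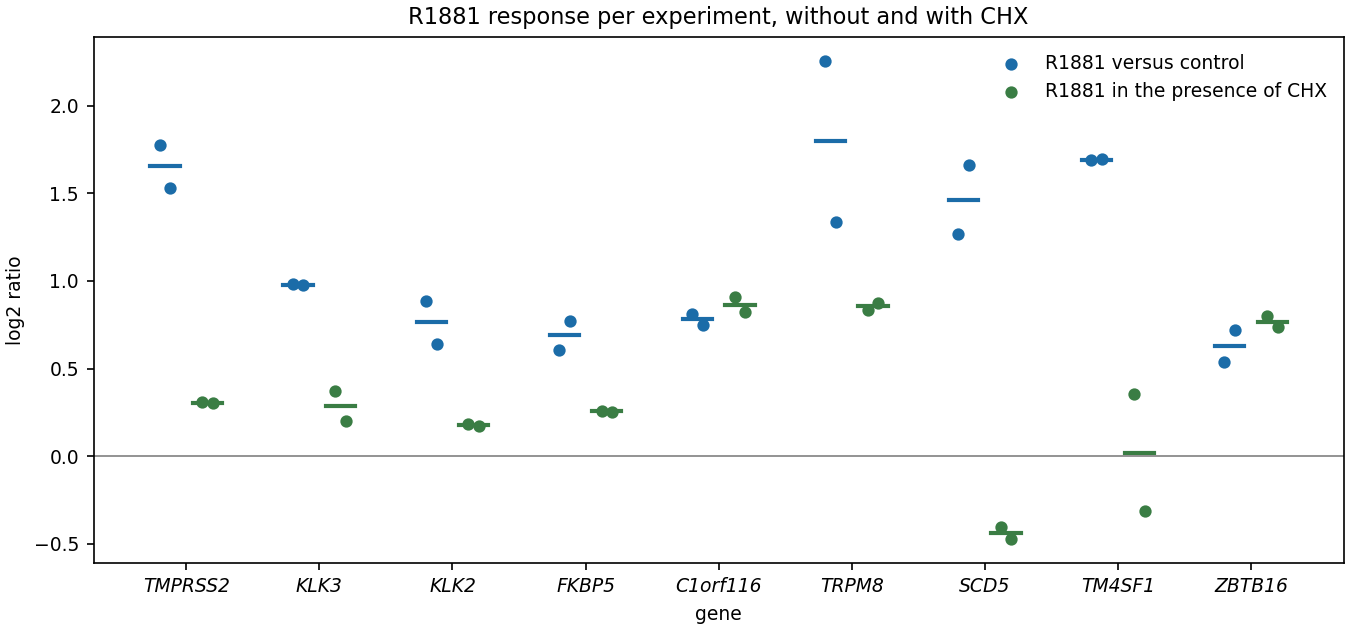
Log2 ratio of 9 genes in R1881 versus control and for R1881 in the presence of CHX. Points are the 2 experiments, each the mean of a dye swap, and bars are their means; TMPRSS2 has 1.65 without and 0.31 with CHX, C1orf116 0.78 and 0.87, and SCD5 1.46 and −0.44.

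Androgen-induced genes rose as a list with R1881 in the presence of CHX (median 0.10, 28 of 36 above 0, medians of 0.09 and 0.11 in the 2 experiments; camera adjusted p = 0.000102, and adjusted p = 0.321 with an estimated correlation). On the direct arrays their median was 0.07 with 28 of 36 above 0, 0 members were called over all genes and 1 rose when adjusted over the list alone. Without experiment 1 of CHX the list had a median of 0.10 and was not called (adjusted p = 0.0538). The cell cycle list had a median of 0.02, ranked down by camera (adjusted p = 0.703), with 30 of 48 above 0. It was called down without experiment 1 of CHX (−0.070) or experiment 2 of CHX plus R1881 (−0.088), and up without experiment 2 of CHX (0.15). Androgen-repressed genes (0.04, adjusted p = 0.0406) and ATF4 targets (0.07, adjusted p = 0.0180) ranked up, and histone (−0.04, adjusted p = 0.0406) and ribosomal protein genes (−0.04, adjusted p = 0.000312) ranked down. With an estimated correlation their adjusted p values were 0.634, 0.705, 0.634 and 0.634, and each of these 4 calls ended without experiment 1 of CHX and without experiment 2 of CHX plus R1881. Scaling the arrays also ended the calls of the androgen-repressed (adjusted p = 0.208), ATF4 (0.0819) and histone lists (0.218). With the experiment as a block, sterol synthesis genes (0.07) and RNAs degraded in step with translation (0.03) were called besides (adjusted p = 0.0304 for both). Without the block and with an estimated correlation their adjusted p values were 0.816 and 0.634. The immediate-early list (0.05, camera adjusted p = 0.120) was not called in the main fit but was called in 4 of 17 alternatives. Fry called 0 of the 19 lists in this contrast.

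Limma called 0 genes for R1881 in the presence of CHX, with 185 at an unadjusted p under 0.05 and 727 expected by chance, and 0 with the experiment as a block. The 4-array fit called 2, the named C1orf116 and ZBTB16. In simulated data the averaged fit called 62.7% of the changes of 1 and 1.49% of those of 0.5 in this contrast. With 200 changed genes simulated, the adjusted threshold was easier to pass than in the measured data. These shares are thus likely too high, and 0 calls do not show that changes of 1 were absent. The log2 changes of the experiments correlated across genes at −0.0307, and those on the direct arrays correlated with the contrast at 0.234 in experiment 1 and 0.0867 in experiment 2.

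The genes that responded to R1881 in the 4-array fit were followed in the presence of CHX. They were picked from the same arrays that give their values without CHX, which makes those values too large in size. In addition, unchanged genes made up 32.2% of the simulated calls of this fit. Part of the drop from without to with CHX is therefore built in, and its size is no measure of what CHX did. The 104 that rose had a median of 0.51 without CHX and 0.09 with it, and 81 of them were above 0 with CHX. Both experiments with CHX were above 0 for 50 of the 104, against 28.1% of all genes, and both direct arrays for 52, against 26.3% of all genes. The 68 that fell had a median of −0.39 without CHX and −0.01 with it, and 37 of them were below 0 with CHX. Both experiments were below 0 for 20, against 21.2% of all genes, and both direct arrays for 39, against 25.4%. Across all genes the responses without and with CHX correlated at 0.00403, against 0.000834 in the simulation, and at 0.0908 and 0.0458 when each came from a different experiment.

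The difference between the R1881 responses without and with CHX was tested directly. Limma called 0 genes, with 356 at an unadjusted p under 0.05 and 727 expected by chance, and 0 with the experiment as a block, and the 4-array fit called 2, SCD5 and TMPRSS2. As a list, the cell cycle genes responded more without CHX (median difference 0.30, 47 of 48 above 0; camera adjusted p = 1.13e-15, and adjusted p = 0.285 with an estimated correlation), and so did the androgen-induced genes (0.16, 27 of 36 above 0; adjusted p = 3.57e-06, and adjusted p = 0.192 with an estimated correlation). With the experiment as a block, ribosomal protein genes (−0.10, adjusted p = 0.0124) and RNAs degraded in step with translation (−0.12, adjusted p = 0.0333) were called besides. Their responses were lower without CHX, and without the block and with an estimated correlation their adjusted p values were 0.798 and 0.285.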

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

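For the patterns weighed here, the test of serum response factor targets had been written down beforehand; the other tests, that of a floor set by CHX among them, were chosen only after the result was seen. A first test of the floor, written beforehand, had picked members by a CHX change that enters the difference it measured (0.33 for 15 members), so it is void and not used. Members picked by CHX plus R1881 (0.31 and 0.084 in the 2 experiments) are void for the same reason, with the opposite sign. Over the 3 comparisons with control, 270 values were tested for 1 array far from the other 3 (3 of whole arrays, 210 of genes and 57 of list medians). Of these, 13 had such an array, and chance gives about 1 in 20. In R1881 versus control, experiment 2 in the first-named Cy3 orientation held CBLN2 at −0.93 (−0.40 to −0.35 on the other arrays), POLH at 0.16 and RANBP10 at −0.62. Experiment 2 in the Cy5 orientation held CXCL2 at −1.16 (−0.02 to 0.06), MCM4 at 0.15 (0.59 to 0.66), MID1 at −0.64, ORC1 at 0.11 (0.44 to 0.50) and PAOX at 1.38 (−0.13 to 0.05), and experiment 1 in the Cy3 orientation held FOXA1 at 0.13 (−0.37 to −0.35). Of the 9 genes, 8 had their far value in experiment 2. In CHX versus control, experiment 2 in Cy3 held ODC1 at 1.88 (1.28 to 1.34) and RRM1 at −1.09 (−1.41 to −1.36), and experiment 1 in Cy5 held the median of the androgen-repressed list at −0.19 (−0.04 to −0.01). In CHX plus R1881 versus control, experiment 2 in Cy5 held RLN1 at −2.14 (−3.51 to −3.45).

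By the camera test of the difference, responses to R1881 without and with CHX differed for 7 lists. It called 2 more with the experiment as a block, and fry called 0 of the 19. The median differences were 0.16 for androgen-induced genes (adjusted p = 3.57e-06; 0.192 with an estimated correlation), −0.17 for androgen-repressed genes (0.000111; 0.192), 0.30 for cell cycle genes (1.13e-15; 0.285), 0.089 for chaperones of the endoplasmic reticulum (0.00982; 0.612), −0.082 for ATF4 targets (0.0156; 0.612), 0.069 for ribosome biogenesis genes (0.00982; 0.285) and −0.13 for respiratory chain genes (0.00345; 0.192). The calls of the first 3 kept their side of the threshold when any 1 experiment of a treatment was left out, and those of the other 4 did not.

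Probes without a gene name, which no comparison uses, also gave calls. There were 2 such probes in R1881 versus control, 2113 in CHX versus control (1080 rose, 1033 fell; 21.3% of 9937, against 35.9% of named probes) and 2097 in CHX plus R1881 versus control.

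Cell cycle transcripts were higher with R1881 alone (median 0.34) and not when CHX was present (0.02). A floor, at which CHX had lowered these transcripts too far for a rise to be measured, and a response that CHX prevents cannot be told apart: the 11 members that CHX did not lower in experiment 1 had a median difference between the responses without and with CHX of 0.27 in experiment 2 (8 above 0), which is 1 experiment. The 23 picked in experiment 2 had 0.31 in experiment 1 (21 above 0), but 12 of them were lowered there. A single experiment or dye orientation is argued against by the array medians, of which the lowest was 0.22. Whether the rise needs newly made protein stays open: the difference of the list had an adjusted p of 0.285 with an estimated correlation, CHX alone lowered these genes (median −0.43), and a slower cell cycle in CHX was not tested.

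Transcripts of ribosomal proteins were slightly lower with R1881 (median −0.15). A dye bias of these probes would cancel in the swap, but the swap-averaged median was −0.090 in experiment 1 and −0.17 in experiment 2. By orientation it was −0.22 in Cy3 and −0.09 in Cy5. Single arrays had −0.17 in Cy3 and −0.006 in Cy5 in experiment 1, and −0.22 and −0.17 in experiment 2. With CHX versus control the list had −0.30 and −0.34 in Cy3 but 0.08 and −0.004 in Cy5, so its value depended on the dye. A dye bias is argued against as the whole cause, while a part due to the dye stays open. If the control RNA held an unusual amount of these transcripts, the contrast in which the control cancels should lie at 0. It had a median of −0.042 (−0.03 and −0.06 in the 2 experiments, −0.02 on the direct arrays), between 0 and −0.15, so a feature of the control RNA and a response to R1881 that CHX dampens cannot be told apart.

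ACTA2, VIM and TAGLN rose with CHX by 4.78 ± 0.23, 2.97 ± 0.18 and 1.20 ± 0.68. Stromal cells in the CHX cultures would bring collagen transcripts too, but the other 12 members of the fibroblast and stroma list had a median of −0.0076, with COL1A1 at −0.23 ± 0.03, COL1A2 at −0.49 ± 0.07 and COL3A1 at −0.29 ± 0.12, which argues against them although COL6A3 rose by 0.59 ± 0.10 (adjusted p = 0.0612 from the Cy3 orientation alone) and SPARC by 0.38 ± 0.21. A hypothesis is that serum response factor, whose own transcript rose by 2.40 ± 0.14, was more active: 19 measured actin cytoskeleton targets of it had a median of 1.11, 16 rose and 0 fell (camera adjusted p = 7.96e-07; adjusted p = 0.212 with an estimated correlation). The largest rises among the 19, named after their values were seen, were VCL by 2.80 ± 0.02, TPM4 by 3.28 ± 0.79 and ACTG2 by 3.44 ± 0.05. CNN1 (0.18 ± 0.13), TGFB1I1 (−0.18 ± 0.08) and PDLIM7 (−0.08 ± 0.09) were not called. The list as a whole goes with that hypothesis, while slower decay of these RNAs in CHX was not tested.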

How the results depend on the processing

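All alternatives were planned except the fit to R1881 arrays alone, the fit within experiments and that to all 14 arrays, which were chosen only after the results were seen. As analysed, 1 gene was called in R1881 versus control (1 rose, 0 fell), 5519 with CHX, 5443 with CHX plus R1881, 0 for R1881 in the presence of CHX, 0 for the difference between the R1881 responses, and 0 changed the same way by R1881 with and without CHX. Scaling the arrays gave 89 for R1881 (48 rose, 41 fell) and 1 for the difference; quantile normalization gave 744 (435 rose, 309 fell), 3419 with CHX, 3496 with CHX plus R1881 and 1 for the difference, SCD5 in both. By construction these settings give all arrays against control 1 common spread, which widens the R1881 arrays and narrows those with CHX. Taking the 4 arrays as separate samples gave 343 for R1881, 3 in the presence of CHX, 8 for the difference and 2 changed the same way. With each dye-swap pair as a random block these were 172, 2, 2 and 2, and with a dye term 379, 4, 11 and 3. Over all 14 arrays they were 342, 8, 39 and 6, with the direct arrays as a block of their own. Each of these fits counts more arrays as samples. For R1881 the replicate block gave 2 (TMPRSS2 and SCD5), the median over probes 2 and the test of each probe 2 (TMPRSS2 and KLK3 in both). The limma fit to the R1881 arrays alone gave 1, TM4SF1 (adjusted p = 0.0492) in place of TMPRSS2 (adjusted p = 0.157). That fit uses only the spread between the R1881 experiments, with an SD of 0.0057 for TM4SF1 and 0.17 for TMPRSS2. The main fit pools it with the spread of the arrays with CHX. A change of at least 1.5-fold left 2985 with CHX and 2986 with CHX plus R1881, and an adjusted p under 0.01 left 3485, 3479 and, for R1881, 0, since both are stricter. Leaving out 1 experiment of a treatment, in which the other is assumed to vary like the other treatments, gave 0 to 0 for R1881 and 3402 to 4218 for CHX plus R1881. It moved the median of the androgen-induced list in the presence of CHX from 0.10 (no call without CHX experiment 1, adjusted p = 0.0538) to 0.15, and that of the cell cycle list from −0.088 to 0.15, where the main value was 0.02 and uncalled. The cell cycle list was called down without CHX experiment 1 (−0.070, adjusted p = 0.0110) and without CHX plus R1881 experiment 2 (−0.088, adjusted p = 0.0225), and up, a reversal, without CHX experiment 2 (0.15, adjusted p = 0.0231), as each contrast then rests on different cultures. The cell cycle list with R1881 (0.34) lost its call with an estimated correlation (adjusted p = 0.148) and by fry (0.0959), and the androgen-induced list in the presence of CHX (0.10) lost it by both (0.321 and 0.240). Sizes moved as well. Over the alternatives, list medians with R1881 ran from 0.22 to 0.87 for cell cycle genes and from 0.15 to 0.61 for androgen-induced genes. For ribosomal protein genes they ran from −0.34 to −0.09. Over all settings, 3189 values of named genes kept direction and side of the threshold, 269 gained a call, 42 lost one and 0 reversed; for lists these were 1306, 63, 112 and 1, and of the counts 75 stayed within 1.5 times and 33 did not. Centring, robust moderation, 1 dye orientation alone and the direct arrays used in experiment 1 moved none of the counts named above by over 1.5 times. Not run: a filter on missing values, as 0 were missing, on dim spots, as the files hold no intensities, the random block for lists, as camera takes none, and single probes for lists and named genes.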

Other observations

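The tests behind the values here were planned, except the fit to all 14 arrays and the fit to the difference within each experiment, which were chosen only after the results were seen. Genes of polyamine metabolism with CHX included several whose proteins are known for rapid turnover: SAT1, the spermidine acetyltransferase, rose by 1.97 ± 0.11, AMD1, the decarboxylase that supplies aminopropyl groups, by 1.54 ± 0.24 and ODC1, ornithine decarboxylase, by 1.45 ± 0.19, while OAZ2, an antizyme, fell by 0.58 ± 0.30, a call lost without experiment 1 of CHX (−0.37, adjusted p = 0.0636). As a list they had a median of 0.30, with 5 of 12 that rose and 1 that fell (6 and 1 adjusted over the list alone). Camera did not call them (adjusted p = 0.109), but fry called them up (adjusted p = 0.000291). Their median was 0.40 in experiment 1 and 0.16 in experiment 2. The respiratory chain list had a median of −0.07 with 8 of 44 that rose and 13 that fell, the same adjusted over the list alone. Camera did not call it (adjusted p = 0.175), but fry called it down (adjusted p = 0.00190). In it 3 nuclear-encoded subunits of cytochrome oxidase fell: COX6C (−2.24 ± 0.04), COX6A1 (−2.12 ± 0.44) and COX6B1 (−1.96 ± 0.23). The call of COX6A1 was lost from the arrays with the first-named RNA in Cy5 alone (−1.58, adjusted p = 0.0572). NDUFV2, a complex I subunit, rose by 0.66 ± 0.02. Ribosome biogenesis genes split evenly, 9 of 29 up and 9 down (10 and 9 adjusted over the list alone), with NOP14 at 1.33 ± 0.00, NHP2 at −1.15 ± 0.15 and RRP12 at −1.13 ± 0.06 (median −0.02, mean 0.01, ranked down by camera, adjusted p = 0.911).

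Markers of cell types and states with CHX also moved gene by gene. Luminal prostate genes had a median of −0.14, with 4 of 10 that fell and 1 that rose, the same adjusted over the list alone (camera adjusted p = 0.109). Androgen-repressed genes had a median of 0.01 and a mean of −0.29 and were ranked down (adjusted p = 0.448), with 3 of 17 that rose and 7 that fell, the same adjusted over the list alone; CCN3, a matricellular protein gene, rose by 2.07 ± 0.09 and BCHE, butyrylcholinesterase, fell by 2.35 ± 0.29. Of 11 basal epithelial genes, KRT5 rose by 0.20 ± 0.07 and NGFR fell by 0.34 ± 0.18, and 0 passed when adjusted over the list alone in limma (list median 0.03, ranked down by camera with an adjusted p of 0.931 and up by fry). Both calls of single genes ended after scaling, with adjusted p of 0.144 for KRT5 and 0.0628 for NGFR, and without experiment 1 of CHX (0.107 and 0.261). Of 13 neuroendocrine genes 3 fell, the same adjusted over the list alone: DDC (−0.84 ± 0.26), ENO2 (−0.96 ± 0.05) and NTS (−0.31 ± 0.11; median 0.02, mean −0.14, ranked down, adjusted p = 0.550), and the calls of ENO2 and NTS ended after quantile normalization (adjusted p = 0.151 and 0.0775) and without experiment 1 of CHX (0.0867 and 0.118). The fibroblast and stroma list had a median of 0.04, with 5 of 15 that rose and 3 that fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.448). Fry called this list up (adjusted p = 0.000291), and the luminal prostate (0.00190) and androgen-repressed lists (0.0125) down. It did not call the basal (0.566) and neuroendocrine lists (0.262).

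TNK2, a tyrosine kinase gene, had 0.91 ± 0.08 with R1881 in the presence of CHX and 0.08 ± 0.02 with R1881 alone. Its adjusted p in the former, 0.904, was the smallest of all genes. ARHGEF26, a guanine nucleotide exchange factor, had 0.94 ± 0.13 in the presence of CHX and 0.48 ± 0.47 without it. When the difference between CHX plus R1881 and CHX was taken within each experiment and fitted alone, limma called 0 genes with 476 at an unadjusted p under 0.05, and TNK2, TRPM8, C1orf116 and ARHGEF26 had the smallest p values (adjusted p = 0.711 for each of the 4). All 4 were among the 8 genes called for this contrast by a fit to all 14 arrays, with ADH6, HMOX1, TGFBR3 and ZBTB16. These names were chosen after their values were seen. The fit to all 14 arrays counts the direct arrays as a further experiment, although they are a dye swap of experiment 1. Its adjusted p values are therefore too small. Both fits use the same cultures, so their overlap is no independent support.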
